A study of Homo sapiens with 9 samples.

How the data were processed

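RNA sequencing of 9 libraries from HK-2 cells, a papillomavirus-transformed human proximal tubule line, was re-analysed from the table of values per gene that the authors deposited. The labels give HK-2 as the cell line of all 9, but their treatment text reads HK-3 for untreated 2 and MYDGF 3 and HK-4 for untreated 3 and MYDGF 4. All are read here as HK-2, as in the cell line entry and the protocols, and this was not tested. The labels place 3 libraries each in untreated cells, cells given aristolochic acid, and cells given a MYDGF adenovirus and aristolochic acid. Table columns were matched to samples by the sample titles, in which NC marks untreated cells, NA the aristolochic acid group and AA the MYDGF group; AA as used elsewhere in the text is the aristolochic acid group, not this column prefix. Per the labels' protocols, 1.3 µg of total RNA went into each library. The labels do not say whether the untreated or the aristolochic acid cells received a control vector, so an effect of MYDGF and an effect of the vector are not separated by this design. They also do not say that the libraries of a group came from separate cultures. All p-values measure only the spread between these samples, which may be technical.

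The deposited table holds whole-number counts per gene, not normalized, per the file headers, and FPKM values beside them. The FPKM values were made by the authors from the counts, a gene length and the total count of the library: for all 37792 genes with an FPKM above 0, the columns gave a single length in all libraries within 0.1%. Per the submitters' processing notes, CASAVA 1.8, HISAT2, SAMtools 1.3.1 and edgeR were used and the genome build was mm10, a mouse build. The table itself lists human Ensembl IDs, and 99.9% of the IDs found in GENCODE 29 overlap that gene's GRCh38 position, so the positions printed here are those of the table and are read as GRCh38. The counting tool, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads from overlapping or antisense genes, and from ribosomal protein genes or mitochondrial genes with near-identical copies, may therefore be split or merged in ways that cannot be seen in the counts.

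The table lists 62703 genes, of which 41737 have a symbol. Genes without a symbol took 1.44 to 1.87% of the counts of a library and stayed in the library totals and in the tests. Of all IDs, 58279 (92.9%) were found in GENCODE 29, which gave the strand and the position for the comparison of neighbouring genes. The gene type is that of the deposited table. Total counts per library ran from 10.9 to 14.3 in units of 1e6. No pair of libraries within a group differed by as little as sampling noise, so all 9 were used as separate samples.

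Groups were compared with edgeR 4.0.16 in R 4.3.3. Counts were scaled with TMM, genes were kept with filterByExpr on the group (minimum count 10, minimum total 15), and a single factor with 3 groups was fitted to all 9 libraries with the quasi-likelihood model (glmQLFit, glmQLFTest). The fit left 6 residual degrees of freedom, tested 18267 genes and gave a biological coefficient of variation of 16.4%. Adjusted p-values are Benjamini-Hochberg values from this test within a comparison, with 0.05 as the threshold. Levels are TMM-normalized CPM (counts scaled to 1e6 per library), given as mean ± SD over 3 libraries, and log2 fold changes carry the standard error (SE) of the fit. A fold against a group without counts was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio of CPM is given with a 95% interval. Intervals and floors cover counting error only.

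The comparisons were aristolochic acid against untreated, MYDGF with aristolochic acid against aristolochic acid, and, as a secondary comparison, MYDGF with aristolochic acid against untreated. Genes that moved back were those called in the first comparison and called in the opposite direction in the second. Both use the aristolochic acid libraries, so unchanged groups sharing those libraries were simulated 20 times, and the overlap of independent lists was computed for each direction. The 3 shared libraries are too few to be split into parts of at least 2.

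The 27 gene lists were fixed before the data were examined: p53 target genes, DNA replication, mitosis, DNA repair, nuclear OXPHOS subunits, mtDNA-encoded mRNAs, the TCA cycle, mitochondrial biogenesis and dynamics, mitophagy, fatty acid oxidation, glycolysis, NRF2 and glutathione genes, the ATF4 integrated stress response, ER chaperones, epithelial dedifferentiation and matrix, proximal tubule function, tubular injury markers, inflammatory NF-kB targets, interferon-stimulated genes, cholesterol biosynthesis, apoptosis regulators, ribosomal proteins, immediate early and heat shock genes, and markers of endothelial cells, of leukocytes, of fibroblasts and mesangial cells, and of distal nephron and podocytes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists within a comparison, then again with an estimated correlation and with fry. Some genes stand in more than 1 list.

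The rule for named genes was also fixed before the data were examined. It takes MYDGF in every library, and the 8 largest rises and 8 largest falls of each main comparison among protein-coding genes with a symbol, an adjusted p under 0.05, a mean CPM of at least 5 over the 6 libraries and CPM of the groups that do not overlap. It adds up to 4 members of each list with the smallest adjusted p, and IDH2, PPARGC1A, HAVCR1, CDKN1A and FN1. Active genes beside these are named for their position.

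Gene length was compared with log2 fold change by Spearman correlation across genes, once with the genomic span in the table and once with the length behind the FPKM values. Genes are not independent replicates, and no p-value is given. The position of genes near silent in untreated cells (mean CPM under 0.5, here over the raw library totals) was compared with that of active genes (at least 10 CPM) among the 19359 protein-coding genes of the table with a GENCODE 29 position, 99.8% of 19407. This last look was chosen after the largest rises had been seen.

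Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, a threshold of 1 on the log2 fold change, fits to the 6 libraries compared, the replicate numbers of the labels as a block, and each library left out in turn. The steps were tested on simulated data in which 100 of the real genes were changed 1.5-fold and another 100 were changed 3-fold. For aristolochic acid against untreated, edgeR recovered 19 of the genes changed 1.5-fold and 71 of those changed 3-fold over 16708 genes, and 2.2% of its calls were false. For MYDGF with aristolochic acid against aristolochic acid, it recovered 15 and 71 over 17592 genes with 6.5% false. For the secondary comparison, it recovered 19 and 81 over 16672 genes with 9.1% false. DESeq2 gave 17.5%, 29.8% and 22.1% false calls in the same 3 tests. This was over the limit of 15% first set for all tools, which was then kept for edgeR and limma-voom only, and DESeq2 serves here only as an alternative. Results of some single genes are not reported here, while counts and tests of lists include all tested members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.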

Results

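The series addresses MYDGF, a secreted growth factor, in kidney tubules and its relation to mitochondrial homeostasis in chronic kidney disease. RNA was sequenced in 3 groups of 3 libraries from cells whose line is given as HK-2 for all 9, although the treatment labels of 4 of them read HK-3 or HK-4. Untreated cells are numbered 1, 2 and 3 in the labels. Cells of the aristolochic acid group, numbered 1, 4 and 6, received 5 µg/ml of this plant toxin, which is taken up by tubule cells and forms DNA adducts, for 48 h after 12 h of serum starvation. The 12 h of serum starvation and 5% serum are given for all 9 libraries, the untreated ones included. Cells of the MYDGF group, numbered 1, 3 and 4, received an adenovirus carrying MYDGF as well as aristolochic acid. Total counts, in units of 1e6, were 12.7, 12.0 and 13.4 in untreated cells, 12.2, 12.9 and 10.9 with aristolochic acid, and 13.0, 12.9 and 14.3 with MYDGF. At least 1 count was found for 25852 to 26012 genes in untreated libraries, 28527 to 30637 with aristolochic acid and 27818 to 28762 with MYDGF.

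MYDGF itself (ENSG00000074842, chromosome 19, 4641374 to 4670362) stood at 124.8, 130.7 and 122.8 CPM in untreated cells. It stood at 104.9, 74.2 and 90.4 CPM with aristolochic acid and at 662.9, 510.2 and 599.1 CPM in the MYDGF group. The rise over the aristolochic acid group was 2.72 on the log2 scale (SE 0.135, n = 3 per group, edgeR adjusted p = 2.74e-05). In the aristolochic acid group MYDGF fell by 0.49 against untreated cells (SE 0.129, adjusted p = 0.00895). The counts do not tell transcripts of the vector from those of the cells' own gene.

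**Figure D1:**
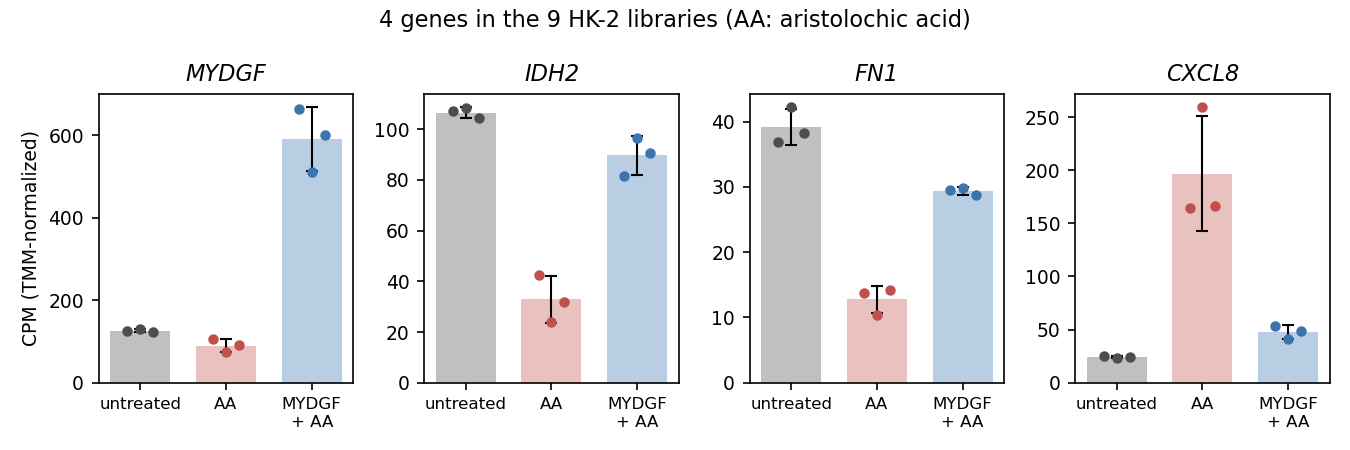
TMM-normalized CPM of MYDGF, IDH2, FN1 and CXCL8 in untreated cells, cells given aristolochic acid (AA) and cells given MYDGF and AA, each on its own linear axis from 0. Points are single libraries, bars the mean of 3 and error bars the SD; MYDGF lies between 510.2 and 662.9 CPM in the MYDGF group.

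The first principal component held 68.8% of the variance of log2 CPM. Untreated libraries lay at -92.5, -92.5 and -95.2 on it, the aristolochic acid libraries at 53.3, 93.4 and 80.7, and the MYDGF libraries between them at 31.3, 0.4 and 21.1. The second component, with 11.8%, set the MYDGF libraries (-36.6, -44.5 and -40.4) apart from both other groups, which ran from 12.9 to 34.5.

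**Figure D2:**
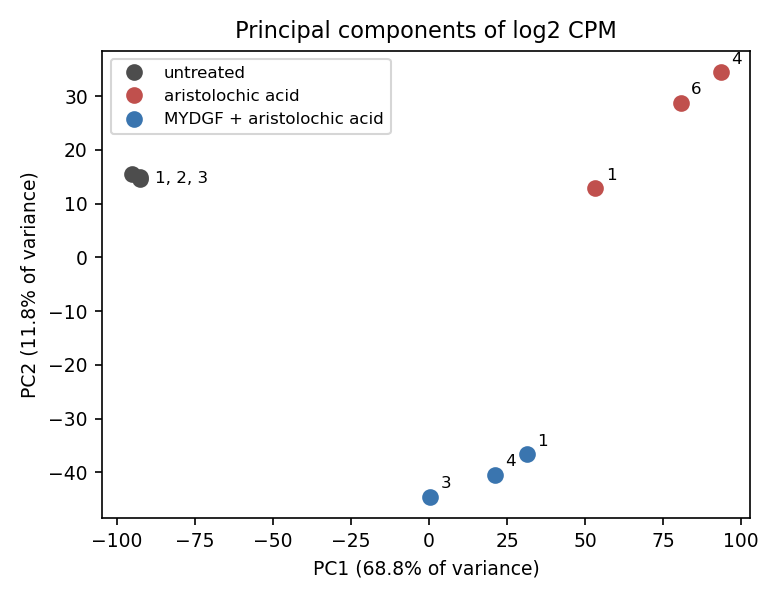
First and second principal components of log2 CPM of the 9 libraries, with the share of the variance on each axis in percent and the labels' library numbers beside the points. Each point is a library, coloured by group; the 3 untreated libraries lie together at the left, and the MYDGF libraries are lowest on the second component.

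The comparison of aristolochic acid with untreated cells addresses how tubule cells given the toxin differ from untreated ones. The sample values used here give untreated cells 0 h of exposure and name neither a vehicle nor a matched time in culture. The toxin is therefore not separated from a solvent, from time in culture or from a control vector, if the treated cells received one. Genes of DNA replication, the ATF4 stress response and NF-kB signalling rose, and mRNAs of mitochondrial DNA, nuclear subunits of oxidative phosphorylation and genes of fatty acid oxidation, the interferon response and cholesterol synthesis fell. As lists these passed camera with the preset correlation, and no list passed with an estimated one (lowest adjusted p = 0.26 with an estimated correlation). The chemokine gene CXCL8 (ENSG00000169429, chromosome 4, 73740519 to 73743716) rose from 24.5 ± 0.829 to 197 ± 54.2 CPM, a log2 fold change of 3.01 (SE 0.187, n = 3 per group, adjusted p = 5.44e-06). The growth arrest gene GADD45A (ENSG00000116717, chromosome 1, 67685201 to 67688334) rose from 28.5 ± 1.28 to 286 ± 104 CPM (3.33, SE 0.233, adjusted p = 8.27e-06). IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase (ENSG00000182054, chromosome 15, 90083045 to 90102477), fell from 107 ± 2.11 to 32.9 ± 9.28 CPM (-1.70, SE 0.172, adjusted p = 4.57e-05). The matrix gene FN1, fibronectin (ENSG00000115414, chromosome 2, 215360440 to 215436073), fell from 39.1 ± 2.74 to 12.8 ± 2.11 CPM (-1.62, SE 0.124, adjusted p = 1.18e-05). Of 18267 genes tested, 5418 rose and 5361 fell, together 59.0%, and 2620 rose and 2004 fell at least 2-fold. CPM of the groups did not overlap for 12041 genes (65.9%), where chance gives 10%.

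Mitochondrial transcripts were lower with aristolochic acid. Of the 13 mRNAs encoded in mitochondrial DNA, 12 fell and 0 rose (median -0.70, camera adjusted p = 6.62e-05, adjusted p = 0.26 with an estimated correlation). The log2 fold change was -0.90 for MT-CYB, the cytochrome b of complex III, -0.85 for MT-ND5 of complex I and -0.75 for MT-CO2 of complex IV. Mitochondrial genes took 6.49 to 6.84% of the counts in untreated libraries and 4.37 to 4.76% with aristolochic acid. Among 74 nuclear-encoded subunits of oxidative phosphorylation, 35 fell and 2 rose (median -0.28, camera adjusted p = 0.00154, adjusted p = 0.468 with an estimated correlation; 34 and 2 when adjusted over the list alone). The complex I subunits NDUFB10 and NDUFB7 fell, at -2.42 and -1.12. Of 25 fatty acid oxidation genes 13 fell and 2 rose (median -0.39, camera adjusted p = 0.0247, adjusted p = 0.26 with an estimated correlation), with ACADVL, which starts the oxidation of very long chains, at -0.92 (SE 0.091). The TCA cycle list (13 of 26 lower, 3 higher, camera adjusted p = 0.0664) did not pass as a list, but IDH3G (-1.53) and the pyruvate carboxylase gene PC (-1.34) fell.

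Genes of mitochondrial upkeep went both ways. Of 27 genes of biogenesis and dynamics 9 rose and 9 fell, and the list's median (0.01) differed in sign from its mean (-0.05) and from the test (camera adjusted p = 0.821). TFAM, which packages mitochondrial DNA, rose by 0.78, while the fission factor MFF (-1.01), the fusion gene MFN1 (-0.66) and the protease gene OMA1 (-1.02) fell. PPARGC1A, a coactivator of mitochondrial biogenesis, had 0 counts in all 9 libraries and was not tested. Among 16 mitophagy genes 6 fell and 2 rose (camera adjusted p = 0.247): PINK1, the kinase that marks damaged mitochondria, fell from 78.9 ± 0.718 to 25.3 ± 4.21 CPM, and BNIP3L fell by 1.15. Of 22 glycolysis genes 11 fell and 6 rose (12 and 6 adjusted over the list alone, camera adjusted p = 0.224), among them PFKL at -1.27 and ALDOC at 2.79. Of 23 NRF2 and glutathione genes 13 fell and 3 rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.0644), and among those that rose was the cystine transporter gene SLC7A11, by 1.08.

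DNA replication genes rose in 27 and fell in 3 of 38 cases (median 0.42, camera adjusted p = 7.12e-05, adjusted p = 0.26 with an estimated correlation), with the licensing factors CDT1 and CDC6 up by 1.44 and 1.40. Of 32 DNA repair genes 17 rose and 3 fell (median 0.26, camera adjusted p = 0.0221, adjusted p = 0.26 with an estimated correlation), a list call also lost with the replicate numbers as a block. The exonuclease gene EXO1 rose by 1.43, while ERCC2 of nucleotide excision repair fell by 0.91. Mitosis genes were split, 10 up and 11 down of 34, with a median of 0.04 that differed in sign from the mean of -0.04 and from the test (camera adjusted p = 0.829): MKI67 rose by 0.57 and KIF20A fell by 1.15. Of 29 p53 target genes 10 rose and 6 fell (camera adjusted p = 0.354). AEN, a nuclease induced by p53, rose by 2.13 and the death receptor gene TNFRSF10B by 0.94. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.67 (SE 0.234, adjusted p = 0.0331), from 69.88 to 76.64 CPM in untreated libraries to 110.38 to 121.86 CPM with aristolochic acid. The call was lost in 9 alternative settings, among them when each single untreated or aristolochic acid library was left out. The fit to the 6 libraries compared was not among these settings. The spread in the main fit also draws on the MYDGF libraries, at 104.3, 213.51 and 221.12 CPM. Apoptosis regulators rose in 7 and fell in 5 of 25 cases (camera adjusted p = 0.387), with TNFRSF10A at 1.25 and BMF at -1.77.

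The ATF4 integrated stress response rose in 19 and fell in 2 of 28 genes (20 and 2 adjusted over the list alone; median 0.80, camera adjusted p = 0.000667, adjusted p = 0.26 with an estimated correlation). STC2 rose from 183 ± 5.21 to 520 ± 3.64 CPM and TRIB3, a pseudokinase induced by ATF4, rose by 1.36. Chaperones of the endoplasmic reticulum went the other way, with 18 of 27 lower and 1 higher (median -0.39, camera adjusted p = 0.000673, adjusted p = 0.306 with an estimated correlation). KDELR3 (-3.98) and HSP90B1 (-0.64) fell. Of 23 NF-kB targets 14 rose and 4 fell (15 and 4 adjusted over the list alone; median 0.76, camera adjusted p = 0.00225, adjusted p = 0.306 with an estimated correlation), among them RELB at 1.34 and LIF at 1.21. Immediate early and heat shock genes rose in 10 and fell in 2 of 19 cases (median 0.58, camera adjusted p = 0.0247, adjusted p = 0.26 with an estimated correlation), a list call also lost with no filter on low counts. FOSL1 rose by 2.27 and DUSP1, a phosphatase of MAP kinases, by 1.38.

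Interferon-stimulated genes had the lowest median of the 27 lists: 23 of 32 fell and 1 rose (median -1.23, camera adjusted p = 4.04e-06, adjusted p = 0.26 with an estimated correlation). IFI35 (-3.41), BST2 (-3.09) and OAS1 (-2.33) were among them. Cholesterol synthesis genes fell in 21 and rose in 0 of 25 cases (median -0.79, camera adjusted p = 5.04e-06, adjusted p = 0.26 with an estimated correlation), with TM7SF2 at -2.11. Ribosomal protein genes were split, 7 up and 10 down of 44 (7 and 9 adjusted over the list alone, camera adjusted p = 0.829), and the dedifferentiation and matrix list likewise, 9 up and 8 down of 22 (10 and 8 adjusted over the list alone, camera adjusted p = 0.829). Outside FN1, the matrix-associated genes CCN1 and CCN2 rose by 1.17 and 1.02.

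Genes of proximal tubule function rose in 13 and fell in 1 of 17 tested cases (median 1.27, camera adjusted p = 0.000709, adjusted p = 0.26 with an estimated correlation). CYP27B1, which activates vitamin D, rose from 4.93 ± 0.335 to 13.8 ± 1.70 CPM, and GATM of creatine synthesis fell by 1.15. Of the 13 that rose, 5 were near silent in untreated cells: the sodium-glucose transporter gene SLC5A1 had 1 count there against 312, a ratio of 326 (counting interval 58 to 1.29e+04). Of these 5, 4 lay within 100 kb downstream of an active gene on their strand, so their rises may or may not be expression of these genes. CYP27B1 was not near silent and lies 50.9 kb past the active gene CTDSP2, and GATM, which fell, lies 77.3 kb past SLC30A4. Another 14 members of the list did not pass the filter. Of 18 tubular injury markers 9 rose and 5 fell (camera adjusted p = 0.387): KRT8 rose by 0.72 and LCN2, a marker of tubular injury, fell by 1.59. HAVCR1, the injury marker KIM-1 (ENSG00000113249, chromosome 5, 157026742 to 157069396), had 2 counts over the untreated libraries and 72 with aristolochic acid, a ratio of 37.6 (counting interval 10 to 316). PROM1 had 1 and 224, a ratio of 234 (counting interval 41.5 to 9.28e+03).

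Among markers of other cell types, members changed in both directions and no list passed camera. Of 6 tested endothelial markers 4 rose and 1 fell (camera adjusted p = 0.095): PECAM1 rose from 0.584 ± 0.0995 to 7.92 ± 3.16 CPM, ESAM by 2.30 and ENG by 3.33, and EGFL7 fell by 1.54. Another 8 endothelial and 12 leukocyte markers did not pass the filter. Of 6 leukocyte markers 3 rose and 1 fell (camera adjusted p = 0.411), with CD79A at 4.51 and CD68 at -1.46. LCP1 rose by 0.61, a call lost in 5 settings: without untreated 1, untreated 2 or aristolochic acid 1, with no filter on low counts, and with the replicate numbers as a block. Of 4 fibroblast and mesangial markers 2 rose and 1 fell (camera adjusted p = 0.821): RGS5 rose by 1.40 and MFAP5 fell by 0.68. Of 8 distal nephron and podocyte markers 4 rose and 2 fell (camera adjusted p = 0.524), with SLC12A3 at 5.08 and PODXL at -1.98.

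The 8 largest rises were in genes without a single count in untreated cells. ARHGAP30 (ENSG00000186517, chromosome 1, 161046946 to 161069970) reached 22.1 ± 6.44 CPM, at least 275-fold higher. PLA2G4F was at least 256-fold higher, GARIN4 253-fold, RSPO2 151-fold, OR5AU1 149-fold, TMEM119 140-fold, and AMPD1 and HDC 133-fold. Among the largest falls, PLPPR3 (ENSG00000129951, chromosome 19, 812488 to 821955) went from 37.9 ± 4.52 to 0.524 ± 0.187 CPM (-6.15, SE 0.394, adjusted p = 5.93e-06). The lectin receptor gene CD302 (-4.91), the monoamine transporter gene SLC29A4 (-4.53), APOL1 (-4.49), RAB26 (-4.42), GDF11 (-4.37), NANOS1 (-4.32) and KDELR3 complete the 8. NANOS1 stood at 2.51 CPM in aristolochic acid library 1 and at 0.31 and 0.28 CPM in libraries 4 and 6, so the size of its fall depends on library 1.

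Many of the genes that rose most lie downstream of an active gene on the same strand. Of 6048 protein-coding genes near silent in untreated cells, 533 rose at least 2-fold, and they made up 36.3% of the 1470 protein-coding genes that rose that much. Of these 533, 434 (81.4%) lay within 100 kb downstream of an active gene on their strand, against 20% of the other near-silent genes. PLA2G4F begins 2.1 kb past VPS39, GARIN4 3.7 kb past ATF3, AMPD1 8.9 kb past NRAS, HDC 9.4 kb past GABPB1 and ARHGAP30 30.6 kb past PFDN2. For TMEM119 the distance was 46.8 kb from CORO1C, for OR5AU1 50.1 kb from HNRNPC and for RSPO2 117.6 kb from EIF3E. Marker genes were among them: CD79A lies 4.2 kb past RPS19, ENG 11.7 kb past AK1, SLC12A3 14.9 kb past NUP93, PROM1 76.1 kb past TAPT1, HAVCR1 78.3 kb past MED7 and SLC5A1 85.4 kb past YWHAH. ALDOC, ESAM and PECAM1 were not near silent and lie 0.3 kb past SPAG5, 4.2 kb past MSANTD2 and 64.0 kb past POLG2. For genes that were not near silent, no share by position was computed. Some that did not rise lie as close, such as CD68, which fell and lies 0.5 kb past EIF4A1. The strand setting of the counts is not given in the sources used here.

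Within 10 kb of an active gene, 125 of 226 near-silent genes (55.3%) rose where the active gene's 3' end faced them on the same strand. The share was 43 of 380 (11.3%) for a 3' end on the opposite strand, 40 of 224 (17.9%) for a 5' end on the same strand and 6 of 143 (4.2%) for a 5' end on the opposite strand. With no active gene within 100 kb, 45 of 2480 (1.8%) rose. Summed over the 226 genes, the level was 30.4 to 33.0 CPM in untreated libraries, 553.6, 1135.8 and 898.8 CPM in aristolochic acid libraries 1, 4 and 6, and 351.1, 203.7 and 276.5 CPM in MYDGF libraries 1, 3 and 4. Other classes rose in sum as well. The 224 genes with a 5' end on the same strand summed to 16.8 to 18.2 CPM in untreated libraries and 141.5, 282.9 and 237.4 CPM with aristolochic acid, and the 2480 genes with no active gene within 100 kb to 80.6 to 84.8 CPM and 201.2, 395.0 and 288.4 CPM.

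**Figure D3:**
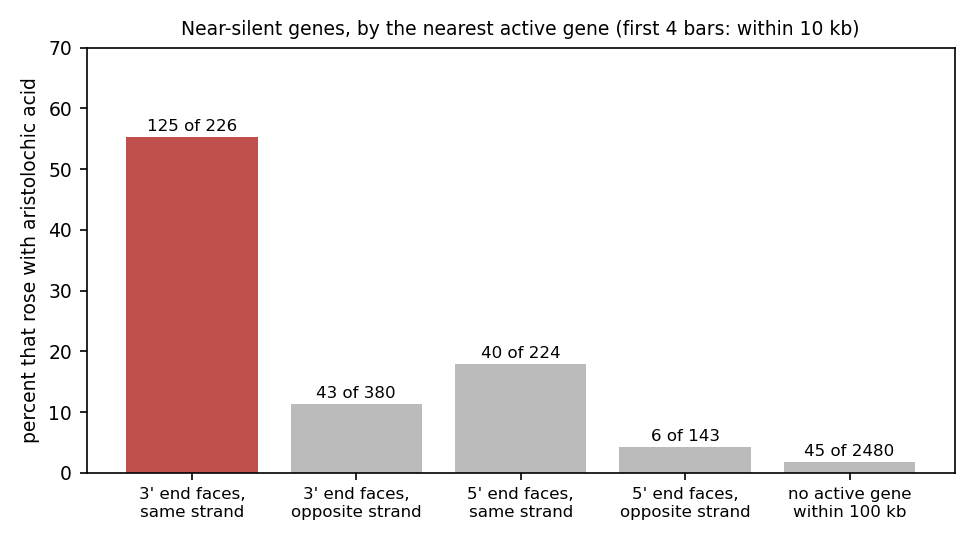
Percent of genes near silent in untreated cells that rose at least 2-fold with aristolochic acid, by which end of the nearest active gene faces them and on which strand, within 10 kb in the first 4 bars and with no active gene within 100 kb in the last. Numbers above the bars are genes that rose of all genes in the class; the highest share is 125 of 226.

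The comparison of MYDGF with aristolochic acid against aristolochic acid addresses what overexpression changed in cells that also met the toxin. NF-kB targets fell as a group, and genes of DNA replication, nuclear subunits of oxidative phosphorylation, and genes of glycolysis and of dedifferentiation and matrix rose. As lists these passed camera with the preset correlation, and no list passed with an estimated one (lowest adjusted p = 0.283 with an estimated correlation). CXCL8 fell from 197 ± 54.2 to 47.7 ± 6.29 CPM, a log2 fold change of -2.04 (SE 0.179, n = 3 per group, adjusted p = 0.00038). IDH2 rose from 32.9 ± 9.28 to 89.7 ± 7.55 CPM (1.45, SE 0.172, adjusted p = 0.00101), and FN1 rose from 12.8 ± 2.11 to 29.4 ± 0.576 CPM (1.20, SE 0.124, adjusted p = 0.000684). In all, 2688 genes rose and 2691 fell, 29.4% of those tested, of which 541 and 1172 at least 2-fold. Without MYDGF library 3 the number of falls was 1678. With the replicate numbers as a block, which left 2 residual degrees of freedom, 8 genes rose and 6 fell, so most single calls of this comparison are lost under it. CPM of the groups did not overlap for 8094 genes (44.3%), where chance gives 10%.

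Of 23 NF-kB targets 18 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.68, camera adjusted p = 1.38e-09, adjusted p = 0.283 with an estimated correlation). CSF2, a myeloid growth factor gene, fell from 44.7 ± 17.6 to 6.55 ± 1.61 CPM, and CCL20 (-0.95) and NFKBIA (-0.80), the inhibitor induced by NF-kB itself, fell too. Of 32 interferon-stimulated genes 10 fell and 1 rose (10 and 3 adjusted over the list alone; median -0.37, camera adjusted p = 0.0489, adjusted p = 0.639 with an estimated correlation), a list call lost in 11 alternative settings. MX1 (-1.44), IRF9 (-1.02) and IRF1 (-0.97) fell. Immediate early and heat shock genes fell in 6 and rose in 2 of 19 cases (7 and 2 adjusted over the list alone; median -0.39, camera adjusted p = 0.0489, adjusted p = 0.283 with an estimated correlation), a list call lost in 12 alternative settings. FOSB (-1.27), JUNB (-0.55) and HSPA8 (-0.41) fell, and JUND rose by 0.56.

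Nuclear subunits of oxidative phosphorylation rose in 22 and fell in 3 of 74 cases (median 0.21, camera adjusted p = 0.0109, adjusted p = 0.625 with an estimated correlation), a list call also lost with the replicate numbers as a block. NDUFB10 rose from 6.34 ± 1.30 to 21.0 ± 5.31 CPM, UQCRQ rose by 0.72 and UQCRC1 by 0.56, and NDUFA8 fell by 0.44. Of the 13 mRNAs encoded in mitochondrial DNA 2 rose and 1 fell (median 0.02, camera adjusted p = 0.945): MT-CO2 rose by 0.24, MT-ATP8 fell by 0.32, and the mitochondrial share of the counts was 4.44 to 4.71%. The TCA cycle list had 5 of 26 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0926), with IDH1 up by 0.94 and MDH2 by 0.32. Fatty acid oxidation had 6 of 25 higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.647), such as ACADVL at 0.68 and ACADS at -0.82. Of 27 genes of biogenesis and dynamics 4 rose and 2 fell (camera adjusted p = 0.647), with POLRMT, the mitochondrial RNA polymerase, at 0.60 and MFN1 at -0.34. Of 16 mitophagy genes 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.945), with BNIP3 at 0.92 and PINK1 at 0.52.

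Glycolysis genes rose in 9 and fell in 2 of 22 cases (11 and 2 adjusted over the list alone; median 0.27, camera adjusted p = 0.0203, adjusted p = 0.593 with an estimated correlation), with PDK1 up by 0.74 and ALDOA by 0.48. This list call was lost without aristolochic acid library 4, as was that of the ribosomal proteins, of which 11 rose and 1 fell of 44 (median 0.16, camera adjusted p = 0.0203, adjusted p = 0.625 with an estimated correlation), with RPL12 at 0.51; the latter was also lost under the block. In the dedifferentiation and matrix list 8 of 22 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.31, camera adjusted p = 0.0203, adjusted p = 0.283 with an estimated correlation). Besides FN1, the matrix genes TNC and COL4A2 rose by 0.91 and 0.34 and the cytokine gene TGFB1 by 0.64. Of 38 DNA replication genes 18 rose and 1 fell (median 0.23, camera adjusted p = 0.000292, adjusted p = 0.283 with an estimated correlation), among them CCNE2, a cyclin of S phase entry, by 1.31 and RFC2 by 0.83.

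Other lists did not pass the test as lists. Of 34 mitosis genes 10 rose and 2 fell (camera adjusted p = 0.188), with PTTG1 at 0.71, and of 32 DNA repair genes 10 rose and 4 fell (camera adjusted p = 0.212), with FANCA at 0.55. Of 29 p53 targets 7 rose and 4 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.486): GDF15 rose by 1.39 and BTG2 by 0.94, and ZMAT3 fell by 0.77. CDKN1A was at 0.65 (SE 0.234, adjusted p = 0.063) and passed under DESeq2 and without MYDGF library 1. Apoptosis regulators rose in 3 and fell in 5 of 25 cases (3 and 6 adjusted over the list alone, camera adjusted p = 0.683), with BMF at 1.29 and TNFRSF10B at -0.56. Of 23 NRF2 and glutathione genes 8 rose and 2 fell (camera adjusted p = 0.164), with HMOX1, the heme oxygenase, at 0.81 and GPX4 at 0.78. The ATF4 list had 7 of 28 higher and 4 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.103), with TRIB3 at 0.79 and MTHFD2 at -0.26. ER chaperones rose in 5 and fell in 0 of 27 cases (camera adjusted p = 0.0926): MANF rose by 0.36, while the calls of CALR (0.27), HSPA5 (0.29) and HSP90B1 (0.22) were each lost without at least 2 single libraries. Of 25 cholesterol genes 5 rose and 1 fell (camera adjusted p = 0.075), with FDPS at 0.48.

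Of 17 proximal tubule genes 5 fell and 0 rose (camera adjusted p = 0.0931): AMN (-1.74) and ANPEP (-1.55) fell, and the fall of SLC5A1 (-0.99) was lost without aristolochic acid 4, aristolochic acid 6 or MYDGF 3. AMN lies 11.2 kb past the active gene TRAF3 and ANPEP 15.2 kb past AP3S2 on their strands. Both had risen with aristolochic acid and were not near silent in untreated cells. Whether reads from the upstream genes add to their counts was not tested. Injury markers fell in 6 and rose in 3 of 18 cases (6 and 5 adjusted over the list alone, camera adjusted p = 0.595), with PROM1 at -2.47 and SOX4 at 1.12. HAVCR1 had 72 and 44 counts, a log2 fold change of -0.85 that did not pass (adjusted p = 0.112). Endothelial markers fell in 4 and rose in 1 of 6 cases (camera adjusted p = 0.245), with PECAM1 at -1.90 and EGFL7 at 1.11. Leukocyte markers rose in 2 and fell in 1 of 6 cases (camera adjusted p = 0.945), with CORO1A at 1.65, LCP1 at 1.21 and CD79A at -1.86. Of 4 fibroblast and mesangial markers 1 fell, MFAP5 at -0.58 (camera adjusted p = 0.798), a call lost in 5 settings. Distal nephron and podocyte markers fell in 4 and rose in 1 of 8 cases (5 and 1 adjusted over the list alone, camera adjusted p = 0.108), with NPHS1 at -1.41 and PODXL at 0.75.

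After MYDGF itself, the largest rises were those of NEURL1B (2.15), NBEAL2 (2.13), ZNF791 (2.09), C11orf86 (2.08), COMTD1 (2.06), the proteoglycan gene CSPG4 (1.98) and FLRT1 (1.96). Among the largest falls, CLDN4, a tight junction gene, went from 25.6 ± 5.51 to 2.21 ± 0.452 CPM (-3.53, SE 0.194, adjusted p = 5.26e-05). The others were KRBA2 (-3.99), OR5AU1 (-3.66), GARIN4 (-3.57), ANKRD35 (-3.19), NRXN2 (-3.10), SRMS (-2.97) and APC2 (-2.96). The fall of OR5AU1 was lost without MYDGF library 4. MYDGF library 1 was well above libraries 3 and 4 for OR5AU1 (2.37 against 0.16 and 0.28 CPM), APC2 (13.63 against 3.67 and 4.24 CPM) and NRXN2 (8.04 against 2.5 and 2.69 CPM). The size of these falls and their order depend on that library. KRBA2 lies 0.8 kb past the active gene RPL26 on its strand, APC2 5.8 kb past RPS15, SRMS 10.6 kb past HELZ2 and NRXN2 41.4 kb past SF1. Of the 533 near-silent genes that had risen with aristolochic acid, 335 fell with MYDGF and 1 rose, and their median was -1.53. These genes were chosen for high values in the aristolochic acid libraries, which are also the reference here, so falls are favoured by that choice.

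**Figure D4:**
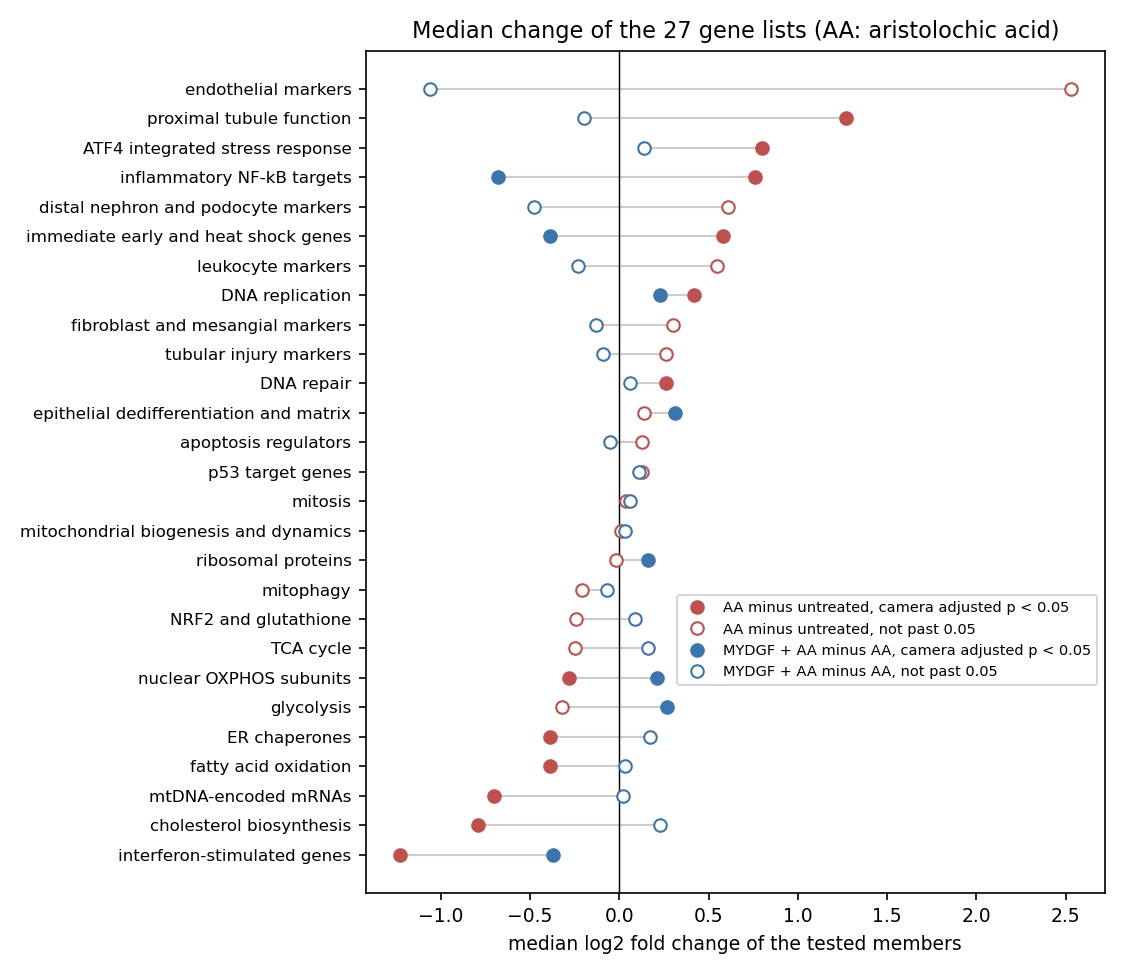
Median log2 fold change of the tested members of each of the 27 gene lists, for aristolochic acid (AA) minus untreated in red and MYDGF with AA minus AA in blue, joined by a grey line. Filled points passed camera with the preset correlation and open points did not; the interferon-stimulated genes lie lowest for AA minus untreated, at -1.23.

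Genes that moved back were counted from both comparisons together, by opposite direction alone, so the count includes genes that went past the untreated level. KRBA2 stood at 8.56 to 11.09 CPM in untreated cells, 50.69 to 99.37 CPM with aristolochic acid and 3.22 to 5.72 CPM in the MYDGF group. MYDGF itself, the overexpressed gene, is also among those that moved back. Of 4085 genes called in both, 3571 (87.4%) moved in opposite directions: 1909 rose with aristolochic acid and fell with MYDGF, among them CXCL8, and 1662 fell and then rose, among them IDH2, FN1 and NDUFB10. Independent lists of these sizes would share 798.2 and 788.9 genes in those directions. Another 514 genes moved the same way in both comparisons. Of these, 293 rose in both, such as STC2 and TRIB3, against 797.3 for independent lists, and 221 fell in both, such as MFN1, against 789.8. Genes moved back made up 33.1% of the aristolochic acid calls and 66.4% of the MYDGF calls. The number of genes moved back was 2328 without aristolochic acid library 4 and 2248 without MYDGF library 3. Those that rose and then fell numbered 1193 without aristolochic acid library 4 and 1173 without MYDGF library 3, and those that fell and then rose 1097 without aristolochic acid library 6 and 1075 without MYDGF library 3.

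Both comparisons share the aristolochic acid libraries, which alone gives opposite moves. The covariance of the log2 fold changes across genes was -0.814, against -0.050 on average for simulated unchanged groups that share those libraries, a difference of -0.764, and the correlation across genes was -0.703 against -0.503. Signs were opposite for 69.9% of all tested genes against 66.8% in the simulations, and 0 genes moved back in any of the 20 simulations. No group differed in these simulations and each gene was drawn independently, so few calls could arise. They do not cover a shift shared by many genes in the aristolochic acid libraries. Part of the excess over independent lists may come from the shared libraries, which are too few to be split.

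Against untreated cells, the MYDGF group differed in 4889 genes that rose and 4440 that fell. Interferon-stimulated genes were lower in 28 and higher in 0 of 32 cases (median -1.30, camera adjusted p = 7.58e-11, adjusted p = 0.229 with an estimated correlation), and all 13 mRNAs of mitochondrial DNA were lower (median -0.61, camera adjusted p = 2.63e-06, adjusted p = 0.25 with an estimated correlation). DNA replication genes were higher in 32 and lower in 1 of 38 cases (median 0.70, camera adjusted p = 3.63e-10, adjusted p = 0.183 with an estimated correlation). NF-kB targets were split, 9 higher and 9 lower of 23 (camera adjusted p = 0.876), and nuclear subunits of oxidative phosphorylation had 15 of 74 lower and 8 higher (camera adjusted p = 0.183).

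Gene length was looked at because bulky DNA adducts stall transcription. The Spearman correlation across genes of the genomic span with the change by aristolochic acid was 0.012 (SD 0.016 over the 3 libraries), and that with the length behind the FPKM values was -0.064 (SD 0.019). In 5 bins of genes from the shortest to the longest span, the median changes were -0.03, -0.08, 0.00, 0.04 and -0.01. For MYDGF against aristolochic acid the correlations were -0.052 (SD 0.021) with the span and -0.011 (SD 0.011) with the FPKM length, the latter -0.032 without aristolochic acid library 4 and 0.006 without library 6. Among genes of mean CPM of at least 5, the correlation of aristolochic acid with the FPKM length turned to 0.020 and that with the span was 0.075, and for MYDGF against aristolochic acid they were -0.081 and -0.128.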

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

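All alternatives were chosen before the data were examined except leaving out libraries for the gene length trend, which was added afterwards. Of the alternative values of the numbers of genes called, the MYDGF change and the length trend, 164 stayed on the same side of their limits, 16 fell short, 5 moved and 1 reversed. Requiring a 2-fold change, which removes smaller changes by construction, left 2620 rises and 2004 falls with aristolochic acid, 541 and 1172 with MYDGF over aristolochic acid, and 2100 and 1325 with MYDGF over untreated. DESeq2, limma-voom, the other scalings, both other filters and fits to the 6 libraries compared kept the numbers of genes called without that requirement within 1.5 times. RLE or upper quartile scaling moved the median of all genes by less than 0.1. These scalings, like TMM, set changes relative to the other genes of a library, which keeps that median near 0. All rises and falls are therefore relative, and a change in the total mRNA per cell would not be seen. Leaving out single libraries gave 1678 (without MYDGF 3) to 3462 (without AA 1, AA being the aristolochic acid group) falls with MYDGF over aristolochic acid, and 2248 (without MYDGF 3) to 4764 (without AA 1) genes moved back, with 2328 without AA 4. By direction, genes that rose and then fell numbered 1173 (without MYDGF 3) to 2658 (without AA 1), and those that fell and then rose 1075 (without MYDGF 3) to 2106 (without AA 1). Of the alternative values of these directional numbers 28 stayed within 1.5 times and 6 fell short, 4 of them without a single library and 2 under the block. Fewer libraries were fitted when 1 was left out, and no further cause was tested. The length correlation for MYDGF over aristolochic acid, on the FPKM length, ran from -0.032 (without AA 4) to 0.006 (without AA 6). Among genes of mean CPM of at least 5, the correlation with the FPKM length reversed to 0.020 for aristolochic acid, and that with the span was 0.075. With MYDGF these were -0.081 and -0.128. The cause was not tested.

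The groups share some replicate numbers. Deviations of same-numbered libraries from their group means correlated at -0.01, 0.02, -0.16, 0.01 and 0.01, which gives no sign that the numbers pair the samples. With 3 libraries per group and no comparison with libraries of unlike number, these values do not exclude a pairing. With the number as a block, 2 residual degrees of freedom remained. Calls were then 2652 up and 2410 down for aristolochic acid, 8 and 6 for MYDGF over aristolochic acid, and 2909 and 2537 for MYDGF over untreated, with 8 genes moved back (3 that rose and then fell, 5 that fell and then rose), and the MYDGF change was 2.78. With so few degrees of freedom, a call lost under the block does not by itself show a weaker effect.

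For the named genes, 3946 alternative values stayed on the same side, 199 fell short (124 of them under the block), 2 newly passed and 0 reversed. For the lists, 721 stayed, 47 fell short (20 of them with an estimated correlation), 42 newly passed (21 of them with fry, which does not compare a list with other genes) and 0 reversed. In simulated data edgeR recovered 19 of 100 genes changed 1.5-fold and 71 of 100 changed 3-fold for aristolochic acid against untreated, over 16708 genes. All other simulated genes were unchanged, and 92 genes were called in all, against 10779 of 18267 in the real data. The adjusted p threshold is stricter where few genes change, so these shares do not give the share missed in the real data. Depth and number of libraries were not varied.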

Other observations

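The tests on neighbouring genes were set down before they were run, after single examples had been noticed in the same data; all other tests here were chosen after the result was seen. For the neighbour tests, the limits on CPM were chosen with that look at the data, and the added condition that the interval of the first ratio stay above 1.5 was set after the counts were seen.

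Some changes ran the same way with aristolochic acid and with MYDGF, rather than back. The hormone gene STC2 rose by 1.51 with aristolochic acid and by another 0.34 with MYDGF, and TRIB3 by 1.36 and 0.79. The autophagy receptor gene NBR1 rose by 0.29 and 0.21, and the actin-bundling gene LCP1 by 0.61 and 1.21, the first of these lost in 5 settings, among them without untreated 1, untreated 2 or aristolochic acid 1 and with no filter on low counts. The fusion gene MFN1 was at -0.66 and -0.34. Other named members of the DNA replication list, CDC6 and CDT1, stood at 1.40 and 1.44 with aristolochic acid and at 0.27 and 0.62 with MYDGF. Not all named members of that list did so. RFC4 ran from 64.35 to 68.54 CPM in untreated cells, 41.34 to 46.23 with aristolochic acid and 62.79 to 71.82 with MYDGF. CCNE1 ran from 18.7 to 19.97, 14.76 to 15.64 and 22.67 to 23.82 CPM. These genes were picked from the named ones after their values were seen.

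Genes near silent in untreated cells rose with aristolochic acid, 533 of 6048. Genomic DNA or unspecific reads in the treated libraries would raise genes far from active ones about as much, but the share that rose with no active gene within 100 kb was 0.0655 times (95% interval 0.0477 to 0.0898) that within 10 kb of an active 3' end. This argues against such reads as the whole cause. The summed level of the 2480 genes far from active ones rose too, with 80.6 to 84.8 CPM in untreated libraries and 201.2 to 395.0 CPM with aristolochic acid, so a smaller part stays open. A candidate explanation is transcripts that run past the 3' ends of active genes: the share that rose was 2.21 times (95% interval 1.64 to 2.98) higher where the active gene's 3' end faced the silent gene than where its 5' end did, a comparison over both strands that could have come out the other way. On the same strand the ratio, added later, was 3.1 (95% interval 2.28 to 4.2). The intervals of these ratios take each gene as an independent unit, although neighbouring genes may share an active gene. They do not measure the spread between libraries. Activity of the silent genes' own promoters was not tested and stays open, since counts per gene do not show where reads lie, so the rises of HAVCR1, SLC5A1, CD79A or ENG may or may not be expression of these genes.

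Genes changed by aristolochic acid moved the opposite way with MYDGF, 3571 of 4085 called in both. The tables argue against chance values that are independent from gene to gene in the shared aristolochic acid libraries: the covariance was -0.814, and the lowest in 20 simulations of unchanged groups was -0.055. A chance shift common to many genes in those libraries was not simulated and stays open. Aristolochic acid library 1 stood at 53.3 on the first principal component, against 93.4 and 80.7 for libraries 4 and 6. Its log2 CPM correlated at 0.972 with library 4 and likewise at 0.972 with MYDGF library 1. Without it, 4764 genes moved back. A weaker response to the toxin along 1 axis does not, by definition, move genes the same way in both comparisons. Genes that did so were 12.6% of those called in both (exact 95% interval 11.6 to 13.6, with genes taken as independent units). This was above the 5% limit set for this test. That limit holds for false calls within a comparison and not among genes called in both, so it does not decide whether these are false calls. For the genes that moved back without passing the untreated level, a weaker response stays open. The median ratio of the change against untreated with MYDGF to that without was 0.71 over all 10779 genes called with aristolochic acid, not over those that moved back alone. By that value a weaker response and an opposing effect cannot be told apart. A weaker response does not take a gene past the untreated level, where KRBA2 went, and such genes were not counted. Whether MYDGF, the adenovirus, a different exposure or a different day of culture could be behind the opposite moves is not separated by this design.

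The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. Every other split mixes the groups compared, so a difference between them adds to the spread within the mixed groups and lowers the calls. The numbers from other splits therefore do not estimate how many calls chance gives. For aristolochic acid against untreated the real split called 10779 genes and the highest other split 1, so 1 of the 10 splits gave as many. For MYDGF against aristolochic acid the numbers were 5379 and 3, again 1 of 10, and for MYDGF against untreated 9329 and 3, 1 of 10. Genes moved back numbered 3571 in the real split. The highest other was 1 among splits of untreated and aristolochic acid libraries, 2 among those of aristolochic acid and MYDGF libraries, and 510 among those of untreated and MYDGF libraries, where both mixed groups are still compared with the real aristolochic acid group.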
